A study of Homo sapiens with 12 samples.

How the data were processed

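Gene expression was measured by RNA sequencing in HEK293 cells, a line derived from human embryonic kidney, after transient transfection with an empty pCDH plasmid or with plasmids for ADAR1, ADAR2 or ADAR3. Per the labels' protocols, total RNA was extracted and made into libraries with a kit for mRNA, and the labels give 3 replicates for each of the 4 groups. The labels do not say whether replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

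The deposited files hold whole-number counts per gene, not normalized, as the values show by their different totals per library. Each has 57820 genes with versioned Ensembl identifiers and 5 summary entries for reads outside genes or not assigned to a single gene. Per the submitters' processing notes, cutadapt 1.14, TopHat2 2.1.1 and Cuffnorm 2.2.1 were used with the hg19 build. The counting program, its strand setting, the annotation release and the read length are not given in the sources used here. The summary entries made up 22.8% to 25.7% of all entries per library and were left out of library sizes and tests. Gene counts per library summed to between 20.7 M and 38.8 M. No gene coordinates are given, because the reference annotation used here is of another build than the files.

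The design fixed before the data were examined assumed FPKM values and named a count test as its fallback, which was applied because the files hold counts. Gene names came from a table of human gene identifiers that matched 51996 of the 57820 genes, of which 39538 have a symbol. Genes were kept with edgeR's filterByExpr at its minimum count of 10 and minimum total of 15, which left 19099 genes. Counts were scaled by the trimmed mean of M values and tested with edgeR 4.0.16 in R 4.3.3, using glmQLFit and glmQLFTest, two-sided. All 12 libraries entered 1 fit with 4 group means and 8 residual degrees of freedom, and the biological coefficient of variation was 9.04%. Benjamini-Hochberg adjusted p-values were taken within each comparison, with a threshold of 0.05, and an adjusted p in the text is edgeR's unless a gene list is named. Levels are counts per 1 M counts (CPM) of the scaled library, as mean ± SD. Folds are those fitted by edgeR, and SE is on the log2 scale.

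Each enzyme was compared with the vector, and the enzymes were compared with each other. The genes named are ADAR, ADARB1 and ADARB2, and then those that passed the test with all 3 libraries of 1 group above all 3 of the other, ranked by the difference in mean log2(CPM + 1). The first 10 in each direction were taken against the vector and the first 5 between enzymes, leaving out small RNAs, duplicated symbols and clone names. For each list described, up to 4 members with the smallest p were named as well. A gene named outside this rule is said to have been chosen after its values were seen.

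The 33 gene lists, fixed with the design, cover interferon, RNA sensing, inflammatory, stress, heat shock, immediate early, p53, cell cycle, sterol, glycolytic, mitochondrial, RNA interference, editing, paraspeckle, splicing, RNA decay, ribosomal, proteasome, lysosome, growth factor, zinc finger and histone genes, and markers of neurons, fibroblasts, blood, other epithelial lines and the kidney and adrenal lineage. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, with a preset correlation of 0.01 and again with an estimated correlation, and with fry of limma, which tests whether a list's genes move on balance in 1 direction. The ADAR family list had 4 tested members and was not tested as a list. Counts of changed members are given over all genes tested and adjusted over the list alone.

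The steps were tested on simulated data for ADAR1 against the vector with 18526 genes and known changes. The test recovered 28 of 65 genes with a simulated log2 change of 0.5, 53 of 65 with 1 and 59 of 65 with 2, and 6 calls, 4.11%, were false. In the simulation of lists, on 19099 genes, the shifted list was called and 0 of the other lists were. Its genes were drawn independently, so it cannot show how often lists of correlated genes are called without a shift. All 12 libraries were also simulated 20 times as unchanged, from the mean levels of the vector libraries. Each gene was drawn independently and with the same dispersion in all groups, to show what sharing 3 controls gives by chance in such data.

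Alternatives were other filters, median-of-ratios and quantile scaling, leaving out the 3 ADAR genes, other treatments of the dispersion, library weights, DESeq2 1.42.0, a replicate block, only the 2 groups compared, a 2-fold minimum, offsets for GC content and transcript length, thinning to the smallest library, and leaving out single libraries or the 2 with the most plasmid reads. GC content and length were those of the longest annotated transcript of each gene.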

Results

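The series compared HEK293 cells carrying an empty pCDH plasmid with cells overexpressing ADAR1, ADAR2 or ADAR3, with 3 libraries per group. ADAR1 and ADAR2 convert adenosine to inosine in double-stranded RNA, and ADAR3 is held to lack this activity. Gene counts per library summed to 20.7 M to 23.3 M in the vector group, 20.9 M to 21.4 M with ADAR1, 27.8 M to 38.8 M with ADAR2 and 26.5 M to 33.7 M with ADAR3. The first principal component held 22.6% of the variance and set ADAR2 replicate 3, and less far ADAR1 replicate 3, apart from the other libraries of their groups. Both lay on the side of the vector libraries, at -33.8 and -14.7 against -20.9 to -17.7. The other enzyme libraries lay at 7.77 to 25.2. On the second component, with 17.6% of the variance, ADAR2 replicate 3 and ADAR1 replicate 3 lay farthest from the vector libraries. They stood at -28.8 and -25.5 there, against 19.4 to 23.5 for the vector libraries. The median SD of log2 CPM was 0.09 in the vector group and 1.56, 2.06 and 1.54 times that in the ADAR1, ADAR2 and ADAR3 groups.

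The transfected genes were examined first, since they check the labels. ADAR (ENSG00000160710.11), which encodes ADAR1, stood at 845 ± 9.27 CPM (SD, n = 3) in vector libraries and at 11287, 18124 and 56575 CPM in the 3 ADAR1 libraries, a 33.9-fold rise (log2 5.08, SE 0.42, adjusted p = 1.74e-05). ADARB1 (ENSG00000197381.11), which encodes ADAR2, went from 28.6 ± 0.65 CPM (SD, n = 3) to 15316, 11909 and 61364 CPM in the ADAR2 libraries (log2 10.01, SE 0.57, adjusted p = 3.76e-08). ADARB2 (ENSG00000185736.11), which encodes ADAR3, went from 1.70 ± 0.28 CPM (SD, n = 3) to 14587, 10407 and 23944 CPM in the ADAR3 libraries (log2 13.22, SE 0.45, adjusted p = 7.2e-12). Replicate 3 held the most transgene reads in each enzyme group, with 5.29%, 5.53% and 2.47% of gene counts. ADARB2 also rose in the ADAR2 libraries, to 6.13, 6.98 and 14.9 CPM (log2 2.43, adjusted p = 0.00707). ADAR did not pass the test in the ADAR2 or ADAR3 libraries, at 952 ± 73.2 and 898 ± 45.8 CPM (SD, n = 3), with adjusted p = 0.83 and 0.909. ADARB1 did not pass with ADAR1 or ADAR3, at 32.3 ± 1.73 and 41.6 ± 1.46 CPM (SD, n = 3), with adjusted p = 0.85 and 0.443. Nor did ADARB2 pass with ADAR1 (adjusted p = 0.308). The spread estimated for these 3 genes includes the variable transgene level, so these tests cannot exclude small changes. ADARB1 stood at 41.1, 43.2 and 40.4 CPM in the ADAR3 libraries and at 32.9, 33.6 and 30.3 CPM in the ADAR1 libraries. Each of these lay above all 3 vector libraries. The same held for ADAR in each ADAR2 and ADAR3 library, while ADARB2 lay below all 3 vector libraries in each ADAR1 library.

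**Figure D1:**
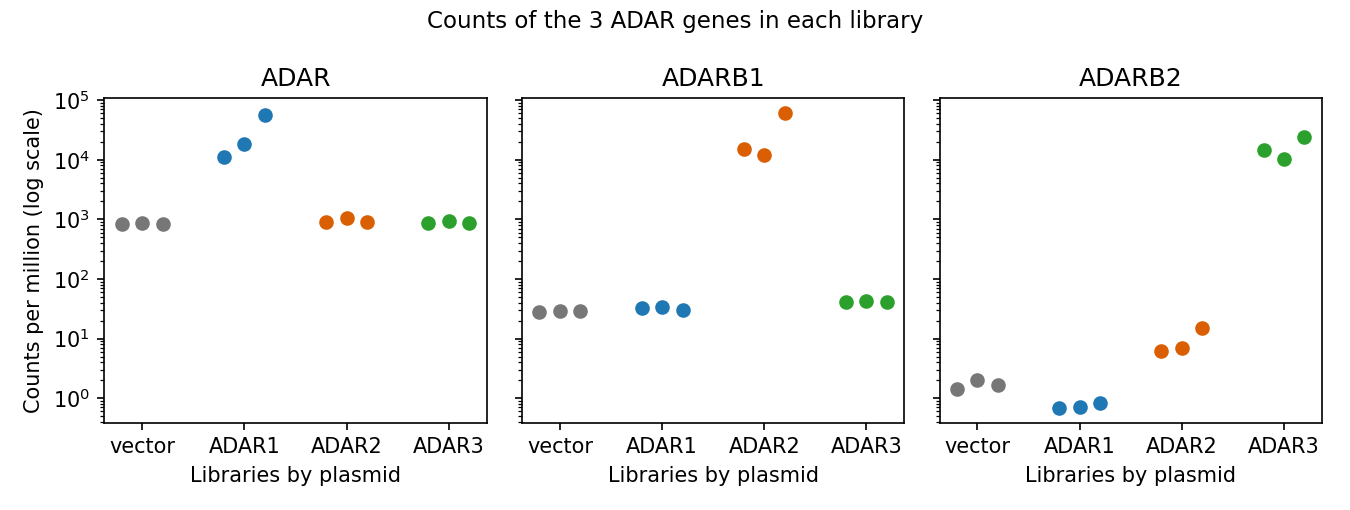
CPM of ADAR, ADARB1 and ADARB2 on a log axis, with 1 point per library and the 4 groups side by side. Each gene stands highest in the 3 libraries transfected with it, and ADARB2 lies between 6.13 and 14.9 CPM in the ADAR2 libraries.

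To ask how ADAR1 changed the transcriptome, its libraries were compared with the vector. LINC01355 (ENSG00000261326.2), a long noncoding RNA, rose 2.78-fold, from 3.81 ± 0.76 to 10.6 ± 1.46 CPM (SD, n = 3) (adjusted p = 0.00113). CYP1A1 (ENSG00000140465.9), a cytochrome P450 induced through the aryl hydrocarbon receptor, was 3.13-fold lower, at 5.89 ± 0.45 against 18.4 ± 1.18 CPM (SD, n = 3) (adjusted p = 0.000113). In all, 455 genes rose and 511 fell among 19099, and 54 and 73 of them changed at least 2-fold. The groups did not overlap in 34.1% of tested genes, where chance gives about 10%, and 70.1% of called genes changed by less than 1.5-fold.

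Among the other named genes that rose, the heat shock protein genes HSPA1B and HSPA1A (2.13- and 2.16-fold) are near-identical and uncertain, since the counting could divide their reads. RUSC1-AS1 (2.31-fold) and SLC16A4-AS1 (2.09-fold) are antisense genes, and without a stated strand setting their reads cannot be told from those of the opposite strand. LINC01287 rose 2.39-fold, CATSPER2, a sperm ion channel subunit, 2.11-fold, and KRTCAP2, a subunit of the oligosaccharyltransferase, 2.01-fold. The pseudogenes SH3GL1P1 (2.38-fold) and FTH1P3 are uncertain as copies of other genes, and FTH1P3 had 0 to 3 counts per vector library, at 0.06 ± 0.07 against 1.24 ± 1.05 CPM (SD, n = 3). Among genes that fell, IRGM, an autophagy GTPase, was 2.97-fold lower, LINC01447 3.23-fold, RFPL4A 2.63-fold, PAPPA2, a protease of IGF-binding proteins, 2.49-fold and TMEM232 2.66-fold. STC1, a secreted glycoprotein, was 2.13-fold lower, CCT6B, a chaperonin subunit, 2.18-fold, and ROCK1P1, a partial copy of ROCK1 and so uncertain, 2.33-fold.

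Of 32 lists, camera called 9 for ADAR1, 3 up and 6 down. Of 40 interferon-stimulated genes, 7 rose and 0 fell (17 and 1 adjusted over the list alone), with a median log2 change of 0.26 (camera adjusted p = 1.99e-09, and adjusted p = 0.606 with an estimated correlation). STAT2 and IRF9, parts of the interferon transcription factor complex, rose 1.59- and 1.67-fold, PARP14 1.35-fold and RSAD2, an antiviral enzyme, 1.33-fold. Of 26 sterol synthesis genes, 6 rose (6 adjusted over the list alone, camera adjusted p = 4.15e-05, and adjusted p = 0.606 with an estimated correlation), among them INSIG1 1.63-fold, MSMO1 1.36-fold, STARD4 1.30-fold and SCD 1.21-fold. Of 19 heat shock genes, 3 rose (4 adjusted over the list alone, camera adjusted p = 0.0227, and adjusted p = 0.836 with an estimated correlation), and DNAJB1 rose 1.61-fold beside HSPA1A and HSPA1B.

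Histone genes had the largest median shift of the called lists with ADAR1, -0.66 on the log2 scale. Of 27 tested, 13 fell (18 adjusted over the list alone, camera adjusted p = 1.35e-12, and adjusted p = 0.0745 with an estimated correlation). H2AC6 was 2.28-fold lower, H2BC5 1.80-fold, H2BC21 1.74-fold and H2BC12 1.34-fold. Histone genes resemble each other in sequence, so that reads could be divided between them. The libraries were made with a kit for mRNA, and how fully it captured histone transcripts is not known. Of 29 glycolysis and hypoxia genes, 8 fell (11 lower and 1 higher adjusted over the list alone, camera adjusted p = 4.6e-09, and adjusted p = 0.606 with an estimated correlation), with BNIP3 1.64-fold, HK2 1.56-fold and PDK1 1.45-fold lower and P4HA1 at a log2 change of -0.59. Of 23 ribosome biogenesis genes, 4 fell (7 adjusted over the list alone, camera adjusted p = 5.01e-06, and adjusted p = 0.606 with an estimated correlation), including RRP12 1.38-fold. The G2 and mitosis list was lower with 2 of 33 genes changed, KIF20A and NEK2 (2 adjusted over the list alone, camera adjusted p = 0.00187, and adjusted p = 0.606 with an estimated correlation). The splicing list was lower with 1 of 31 genes changed, SRSF6 (1 adjusted over the list alone, camera adjusted p = 0.00321, and adjusted p = 0.768 with an estimated correlation). Of 22 p53 targets, FAS, GADD45A, DDB2 and AEN fell (5 adjusted over the list alone, camera adjusted p = 0.0171, and adjusted p = 0.768 with an estimated correlation).

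Camera did not call the other 23 lists with ADAR1 (adjusted p = 0.0609 to 0.862), although some of their members changed. Those lists were RNA sensors, NF-kB targets, the integrated stress response, immediate early genes, S phase genes, mitochondrially encoded and nuclear OXPHOS genes, RNA interference genes, genes with recoding editing sites, genes with edited Alu repeats, ADAR partners, paraspeckle components, RNA decay, autophagy and lysosome, proteasome, TGF-beta and YAP targets, ribosomal proteins, zinc finger genes, and the markers of neurons, fibroblasts, blood, other epithelial lines and kidney and adrenal lineage. MDM4, which restrains p53, rose 1.57-fold, EIF2AK2, the RNA-activated kinase PKR, 1.34-fold and XIAP 1.21-fold, and all 3 are among the genes with edited Alu repeats. The nuclear RNAs NEAT1 and MALAT1 rose 1.63- and 1.75-fold while PSPC1, a paraspeckle protein gene, was 1.30-fold lower. Of 22 neuronal markers, CHGA, CHGB, SNAP25 and NEFH fell, by 1.90-fold in the case of CHGA. SESN2 and PPP1R15A, of the integrated stress response, were 1.49- and 1.51-fold lower. The median, mean and test differed in sign for 3 uncalled lists: paraspeckle components, fibroblast markers, and autophagy and lysosome. With an estimated correlation camera called 0 lists, with 1 below an unadjusted p of 0.05, and fry of limma called 3.

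Without vector replicate 1, 2 or 3 the count of 966 genes was 111, 201 and 121, and without ADAR1 replicate 1, 2 or 3 it was 128, 241 and 767. Of the 75 gene results named for ADAR1 that passed, 27 passed in all 6 of these fits, among them LINC01355, CYP1A1, ROCK1P1, MDM4, NEAT1, STAT2, SESN2 and H2AC6, and 13 passed in none.

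To ask how ADAR2 changed the transcriptome, its libraries were compared with the vector in the same way. KCNJ9 (ENSG00000162728.4), a potassium channel subunit, was 3.76-fold lower, at 8.73 ± 2.88 against 32.4 ± 5.13 CPM (SD, n = 3) (adjusted p = 0.000468). RGS11 (ENSG00000076344.11), a regulator of G protein signalling, was 4.27-fold lower, at 2.47 ± 0.77 against 10.4 ± 1.38 CPM (SD, n = 3) (adjusted p = 0.000468). INSIG1 (ENSG00000186480.8), a regulator of sterol synthesis, rose 1.75-fold, from 219 ± 7.64 to 383 ± 108 CPM (SD, n = 3) (adjusted p = 0.0108). In all, 350 genes rose and 385 fell, 16 and 49 of them at least 2-fold. The groups did not overlap in 25.5% of tested genes, where chance gives about 10%, and 76.3% of called genes changed by less than 1.5-fold.

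LINC01355 rose 2.18-fold and HSPA1B 1.84-fold with ADAR2, the second again uncertain. SLIT3, a secreted guidance protein gene, rose 2.84-fold, CRHR1, a hormone receptor gene, 2.38-fold, CD37, a tetraspanin gene, 1.96-fold, SLC16A7, a monocarboxylate transporter gene, 1.71-fold and SLC66A3 1.75-fold. The pseudogene SSPOP rose 1.93-fold and the antisense gene RUSC1-AS1 1.77-fold. AMD1P3, a pseudogene of AMD1 and so uncertain, was 3.97-fold lower, at 3.37 ± 0.82 against 13.2 ± 1.06 CPM (SD, n = 3) (adjusted p = 1.82e-05), while AMD1 itself did not pass (log2 0.04, adjusted p = 0.83); AMD1 was chosen after its values were seen. IRGM was 3.34-fold lower, CYP1A1 2.61-fold, LINC01447 3.14-fold, RFPL4A 2.55-fold, DISP3 2.38-fold and the antisense gene CCDC13-AS2 2.35-fold, and H2AC6 had a log2 change of -1.07.

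Camera called 6 lists for ADAR2, 2 up and 4 down, and 16 without ADAR2 replicate 3. Of 40 interferon-stimulated genes, 6 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 4.73e-10, and adjusted p = 0.661 with an estimated correlation); PARP14, RSAD2, SAMD9 and STAT2 rose 1.37-, 1.36-, 1.31- and 1.45-fold. Of 26 sterol synthesis genes, 5 rose (10 adjusted over the list alone, camera adjusted p = 1.35e-07, and adjusted p = 0.661 with an estimated correlation), with MSMO1 1.48-fold, STARD4 1.34-fold and SCD 1.22-fold higher. Of 27 histone genes, 11 fell (15 adjusted over the list alone, camera adjusted p = 4.73e-10, and adjusted p = 0.154 with an estimated correlation), with H2BC12 1.38-fold, H2BC5 1.65-fold and H2BC21 1.64-fold lower. Of 23 ribosome biogenesis genes, 6 fell (9 adjusted over the list alone, camera adjusted p = 5.28e-08, and adjusted p = 0.661 with an estimated correlation), with RRP12 1.52-fold and RRP9 1.38-fold lower. Of 29 glycolysis and hypoxia genes, 3 fell (7 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.000104, and adjusted p = 0.755 with an estimated correlation), namely SLC2A1, PDK1 and HK2, by 1.34-, 1.29- and 1.45-fold. Of 31 splicing genes, SF3A1 and SRSF6 fell (3 adjusted over the list alone, camera adjusted p = 0.000281, and adjusted p = 0.755 with an estimated correlation).

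Among the 26 lists not called with ADAR2 (camera adjusted p = 0.0735 to 1), EIF2AK2 and RIGI, sensors of viral RNA, rose 1.31- and 1.34-fold, and CGAS, a DNA sensor, was 1.74-fold lower. The neuronal markers CHGB, CHGA, SYN1 and NEFH were 2.13-, 1.96-, 1.66- and 1.46-fold lower, and SESN2 1.41-fold. MDM4 rose 1.45-fold. The median, mean and test differed in sign for 4 of these lists: NF-kB targets, recoding sites, fibroblast markers, and kidney and adrenal lineage. With an estimated correlation camera called 0 lists, with 1 below an unadjusted p of 0.05, and fry of limma called 3.

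The count of 735 genes fell to 32, 62 and 77 without vector replicate 1, 2 or 3 and to 475 and 213 without ADAR2 replicate 1 or 2, and it was 2722 without ADAR2 replicate 3, the library with the most transgene reads. Of the 70 named gene results for ADAR2 that passed, 12 passed in all 6 of these fits, among them KCNJ9, RGS11, AMD1P3, CYP1A1, RRP12, MSMO1 and CHGB.

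For ADAR3 against the vector, genes of interferons and chemokines led the rise, and the pseudogene AMD1P3, KCNJ9 and RGS11 led the fall. IFNL1 (ENSG00000182393.2), a type III interferon gene, rose 3.34-fold, from 13.3 ± 1.1 to 44.3 ± 14.5 CPM (SD, n = 3) (adjusted p = 0.0163), and IFNB1 (ENSG00000171855.5), the type I interferon beta gene, 2.87-fold (adjusted p = 0.0244). Of glycolytic genes, LDHA (ENSG00000134333.9), lactate dehydrogenase A, was 1.87-fold lower, at 407 ± 57.8 against 760 ± 49.1 CPM (SD, n = 3) (adjusted p = 0.0106). In all, 483 genes rose and 462 fell, 52 and 18 of them at least 2-fold, and the balance depended on the setting, with 1200 and 674 with no filter on low counts, 133 and 59 with no abundance trend, 730 and 501 with a mean of at least 5 CPM, and 829 and 1052 with DESeq2. The groups did not overlap in 36.4% of tested genes, where chance gives about 10%, and 77.2% of called genes changed by less than 1.5-fold.

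The chemokine genes CXCL10 and CXCL11 rose 3.36- and 2.73-fold with ADAR3, and IFNL2 and IFNL3, near-identical and so uncertain, 3.51- and 3.31-fold. With 1 library left out CXCL10 and CXCL11 passed in 0 of 6 fits, with lowest adjusted p = 0.052 and 0.0549, IFNB1 in 1, IFNL1 and IFNL2 in 2 and IFNL3 in 3. IFNL1 stood at 54.1, 51.2 and 27.7 CPM in the 3 ADAR3 libraries, and in each enzyme group IFNL1, IFNB1 and CXCL10 were lowest in replicate 3, the library with the most transgene reads. These genes did not pass with ADAR1 or ADAR2, where IFNL1 stood at 24.9 and 26.2 CPM (adjusted p = 0.14 and 0.11), and IFNL1 did not differ detectably between ADAR3 and ADAR1 or ADAR2 (adjusted p = 0.27 and 0.24). SMTNL1 rose 2.36-fold, ADAMTS10, a metalloprotease gene, 2.39-fold, NUPR1, a stress-induced nuclear protein gene, 2.31-fold and SH3RF2 2.08-fold. RGS11 fell with a log2 change of -1.77, KCNJ9 was 2.99-fold lower, CYP1A1 2.41-fold, STC1 2.12-fold, LINC01447 2.48-fold and CGA, the glycoprotein hormone alpha subunit gene, 2.02-fold. The pseudogenes AMD1P3 (3.68-fold lower), RPL18AP3 (2.37-fold) and HIGD1AP13 (4.88-fold) are uncertain as copies of other genes.

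**Figure D2:**
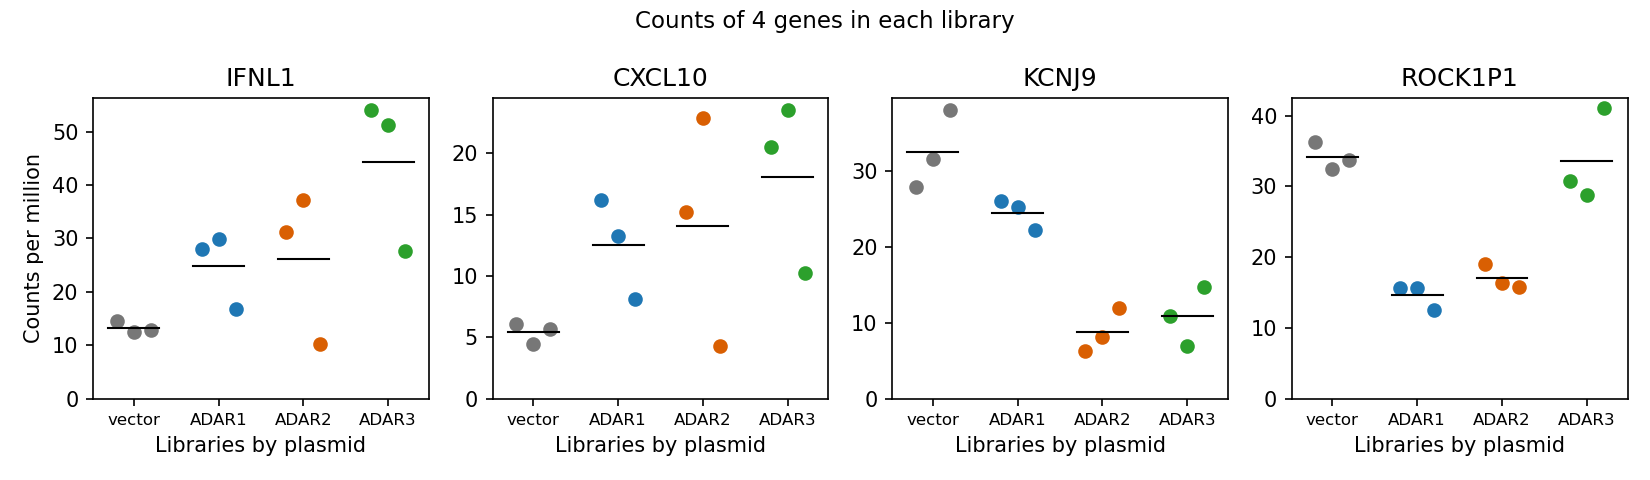
CPM of IFNL1, CXCL10, KCNJ9 and ROCK1P1 with 1 point per library, the 4 groups side by side and a line at each group mean. IFNL1 lies at 27.7 to 54.1 CPM in ADAR3 libraries, and KCNJ9 is low in both the ADAR2 and ADAR3 groups.

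Camera called 16 lists for ADAR3, 3 up and 13 down. Of 40 interferon-stimulated genes, 8 rose (17 adjusted over the list alone, camera adjusted p = 1.85e-11, and adjusted p = 0.398 with an estimated correlation), with STAT2 1.66-fold, PARP14 1.33-fold, RSAD2 1.34-fold and SP110 1.25-fold higher. Of 18 NF-kB targets, CXCL10 and CSF1, a macrophage growth factor gene, rose (2 adjusted over the list alone, camera adjusted p = 0.0238, and adjusted p = 0.636 with an estimated correlation). Of 22 p53 targets, FDXR rose (2 adjusted over the list alone, camera adjusted p = 0.0147, and adjusted p = 0.637 with an estimated correlation).

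Of 29 glycolysis and hypoxia genes, 16 fell with ADAR3 (21 lower and 1 higher adjusted over the list alone), with a median of -0.47 (camera adjusted p = 7.4e-14, and adjusted p = 0.398 with an estimated correlation); LDHA, PGK1, P4HA1 and SLC2A1 were 1.87-, 1.83-, 1.52- and 1.40-fold lower. Of 33 G2 and mitosis genes, 12 fell (21 adjusted over the list alone, camera adjusted p = 3.35e-13, and adjusted p = 0.398 with an estimated correlation), with KIF20A 1.38-fold, CCNB1 1.30-fold, BUB1B 1.26-fold and CCNA2 1.24-fold lower. Of 31 S phase genes, 6 fell (10 adjusted over the list alone, camera adjusted p = 2.93e-08, and adjusted p = 0.398 with an estimated correlation), among them PCNA, the sliding clamp gene, RFC3, RRM1 and RRM2. Of 31 splicing genes, 9 fell (25 adjusted over the list alone, camera adjusted p = 5.97e-12, and adjusted p = 0.398 with an estimated correlation), among them SNRPE, U2AF2, HNRNPA1 and SNRNP200. Of 81 ribosomal protein genes, RPS23, RPS13 and RPS27L fell (17 adjusted over the list alone, camera adjusted p = 1.19e-14, and adjusted p = 0.464 with an estimated correlation), and RPS27L is a paralog of RPS27. Of 27 proteasome genes, PSMA4 and PSMC5 fell (22 adjusted over the list alone, camera adjusted p = 2.27e-10, and adjusted p = 0.427 with an estimated correlation). Ribosome biogenesis had 1 gene lower, RRP12 (15 adjusted over the list alone, camera adjusted p = 5.71e-10, and adjusted p = 0.398 with an estimated correlation), and nuclear OXPHOS genes 1, SDHD (12 adjusted over the list alone, camera adjusted p = 3.89e-08, and adjusted p = 0.464 with an estimated correlation).

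Further lists were called lower with ADAR3. HNRNPL, DHX15 and DHX9 fell among 27 ADAR partners (11 adjusted over the list alone, camera adjusted p = 3.2e-07, and adjusted p = 0.398 with an estimated correlation), and H2AC6 and H2BC12 among 27 histone genes (8 adjusted over the list alone, camera adjusted p = 0.000241, and adjusted p = 0.398 with an estimated correlation). Of 14 paraspeckle components 3 fell, HNRNPH3 and PSPC1 among them, while NEAT1 and MALAT1 rose 1.40- and 1.55-fold (8 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.00288, and adjusted p = 0.464 with an estimated correlation). Of 19 heat shock genes 0 changed (camera adjusted p = 0.00534, and adjusted p = 0.637 with an estimated correlation), and SMG8 fell among 24 RNA decay genes (2 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.0166, and adjusted p = 0.487 with an estimated correlation). Among the 16 lists not called (camera adjusted p = 0.135 to 0.815), EIF2AK2, RIGI and IFIH1 rose 1.28-, 1.30- and 1.28-fold, and MDM4 1.48-fold. The stress genes SLC7A11 and CHAC1 rose 1.61- and 1.41-fold. The median, mean and test differed in sign for 2 of them, recoding sites and other epithelial line markers. With an estimated correlation camera called 0 lists, with 2 below an unadjusted p of 0.05, and fry of limma called 7. Under quantile scaling the medians of 9 of the 16 lists moved by over 1.5 times, 8 of them nearer 0.

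The count of 945 genes was 8, 22 and 5 without vector replicate 1, 2 or 3, and 802, 80 and 92 without ADAR3 replicate 1, 2 or 3. Of the 81 named gene results for ADAR3 that passed, 4 passed in all 6 of these fits, ADARB2, AMD1P3, CYP1A1 and RGS11, and 24 passed in none.

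**Figure D3:**
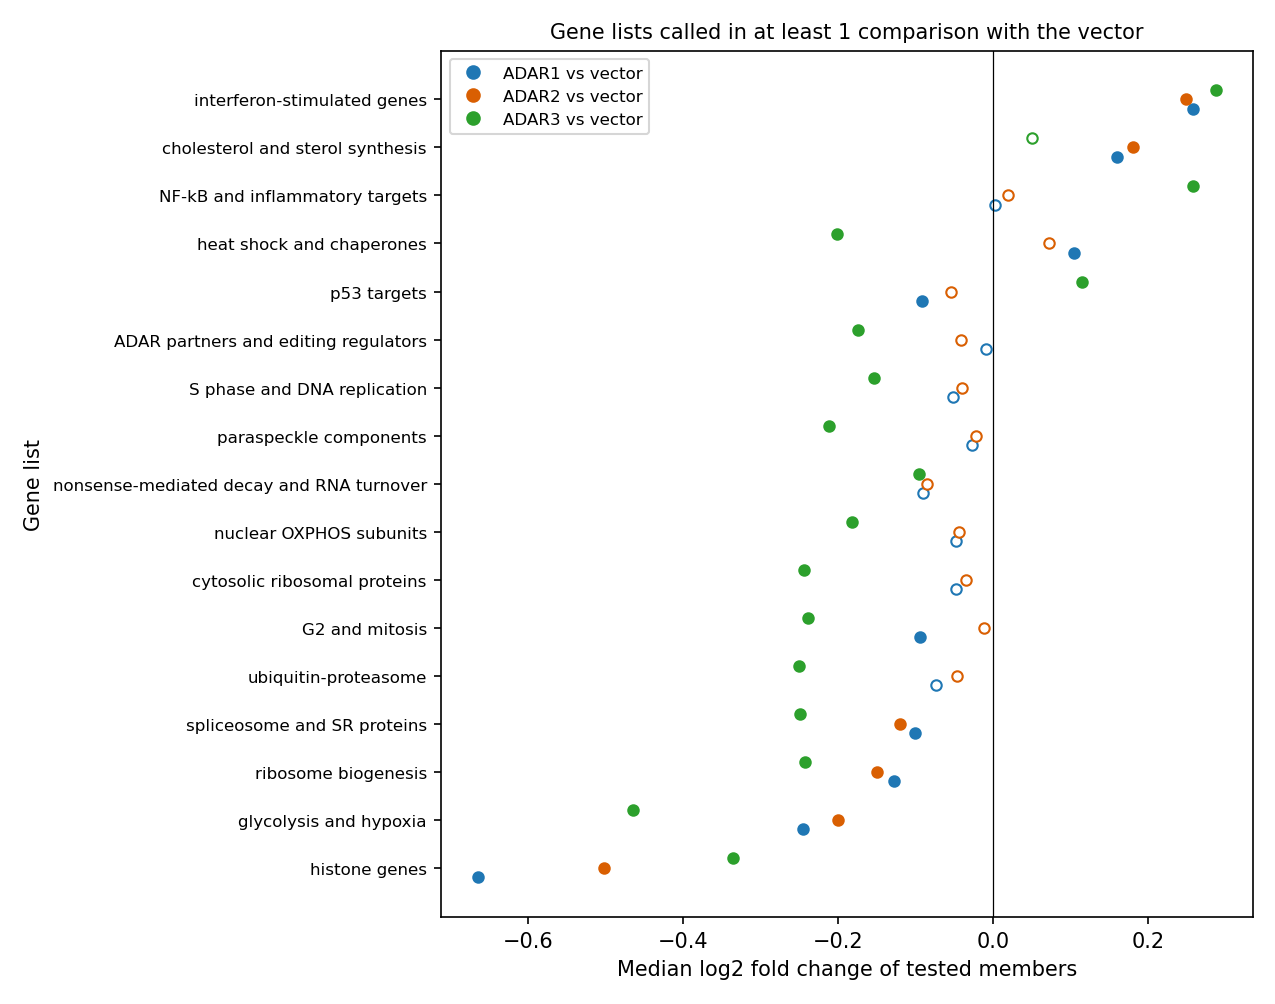
Median log2 fold change of the tested members of each list called in at least 1 comparison with the vector, with 1 point per enzyme, filled where camera called the list. Histone genes lie lowest for ADAR1, at -0.66, and ADAR2, and glycolysis and hypoxia genes for ADAR3, at -0.47, while interferon-stimulated genes lie near 0.26, 0.25 and 0.29.

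The 3 comparisons with the vector were then set side by side. In all 3, 118 genes rose and 73 fell, 191 genes in all, among them CYP1A1, LINC01355, H2AC6, STAT2, PARP14, RSAD2, MDM4 and EIF2AK2. ADAR1 and ADAR2 shared 212 higher and 239 lower genes, where independent lists would share 8.34 and 10.3. ADAR1 and ADAR3 shared 211 and 106 (11.5 and 12.4 for independent lists), and ADAR2 and ADAR3 shared 143 and 102 (8.85 and 9.31). In edgeR's test 0 genes were called in opposite directions by any pair of enzymes, and at an unadjusted p of 0.05 there were 0 for ADAR1 and ADAR2, 17 for ADAR1 and ADAR3 and 11 for ADAR2 and ADAR3. DESeq2 called 0, 4 and 1. Across genes, which are not independent replicates, the fold changes of ADAR1 and ADAR2 correlated at r = 0.764, those of ADAR1 and ADAR3 at 0.669 and those of ADAR2 and ADAR3 at 0.671. Simulated unchanged groups, set against vector libraries that were simulated too, gave mean r of 0.512, 0.510 and 0.539 and 0 shared calls in 20 simulations. The covariance was 0.0943, 0.0822 and 0.0758, against 0.0281, 0.0280 and 0.0284 simulated, which leaves differences of 0.0662, 0.0543 and 0.0474. The 3 vector libraries cannot be divided into parts of at least 2, so how much of the excess overlap comes from the shared controls is not known. The 191 genes became 2, 6 and 2 without vector replicate 1, 2 or 3, 55 and 64 without ADAR1 replicate 1 or 2, 117, 119 and 753 without ADAR2 replicate 1, 2 or 3, and 40 and 48 without ADAR3 replicate 2 or 3.

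Direct comparisons between enzymes asked where their effects differ. ADAR2 differed from ADAR1 in 7 genes. KCNJ9 was 2.83-fold lower with ADAR2 (adjusted p = 0.0109), RGS11 3.32-fold lower (adjusted p = 0.00672) and AMD1P3, uncertain as a pseudogene, 2.96-fold lower (adjusted p = 0.000486). The others were ADAR, ADARB1, ADARB2 and 1 gene with no symbol. Of 32 lists, camera called 2, both higher with ADAR2 than with ADAR1: G2 and mitosis (median 0.07, camera adjusted p = 0.000236) and glycolysis and hypoxia (median 0.10, camera adjusted p = 0.000273), with 0 changed members in either and adjusted p = 0.983 with an estimated correlation for both. The other 30 lists had camera adjusted p = 0.158 to 0.966, and for 8 of them the median, mean and test differed in sign. With an estimated correlation 0 lists were below an unadjusted p of 0.05, and fry of limma called 0. At an unadjusted p of 0.05 edgeR gave 620 genes, and the groups did not overlap in 6.84% of genes, where chance gives about 10%. Of the 6 genes with a symbol, ADAR, ADARB1 and AMD1P3 passed in all 6 fits with 1 library left out, ADARB2 in 4, and KCNJ9 and RGS11 in 2. The count of genes was 3 without ADAR1 replicate 1 or 2, 4 without ADAR2 replicate 1 or 2, and 4 with the 3 ADAR genes left out. The count of 2 lists was 14 and 6 without ADAR1 replicate 1 or 3, and 8 and 18 without ADAR2 replicate 1 or 3.

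Between ADAR3 and ADAR1, 50 genes were higher with ADAR3, ADARB2 among them, and 8 lower, ADAR among them. ROCK1P1, uncertain as a partial copy of ROCK1, was 2.29-fold higher, at 33.6 ± 6.58 against 14.6 ± 1.84 CPM (SD, n = 3) (adjusted p = 0.000243), and stood at 34.1 ± 1.93 CPM in vector libraries. BEST1, a chloride channel gene, was 2.47-fold higher and INHBE, an inhibin subunit gene, 2.36-fold. ASNSP1, a pseudogene, was 3.11-fold higher and the antisense gene VLDLR-AS1 3.50-fold. KCNJ9, RGS11 and AMD1P3 were 2.25-, 2.65- and 2.74-fold lower, the antisense gene SLC16A4-AS1 1.72-fold and the pseudogene HIGD1AP13 3.63-fold. The groups did not overlap in 19.8% of genes, where chance gives about 10%.

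Camera called 19 lists between ADAR3 and ADAR1, 6 up and 13 down, with adjusted p = 0.339 to 0.585 with an estimated correlation. Of 30 integrated stress response genes, CHAC1, TRIB3 and SESN2 were higher with ADAR3 (9 adjusted over the list alone, camera adjusted p = 0.00105), by 1.68-, 1.44- and 1.47-fold. Of 22 p53 targets, DDB2 and AEN were higher (7 adjusted over the list alone, camera adjusted p = 2.74e-10). Of 22 neuronal genes, SNAP25, a synaptic protein gene, was 1.88-fold higher (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0325). Histone genes were higher (median 0.42, camera adjusted p = 1.59e-07), with 0 genes past the test over all genes and 3 adjusted over the list alone, and heat shock genes were lower (median -0.38, camera adjusted p = 2.3e-11), with 0 and 13; under quantile scaling the heat shock median was -0.22. NF-kB targets (camera adjusted p = 0.00679) and zinc finger genes (camera adjusted p = 0.000443) were the other lists called higher. Also lower with ADAR3 were ribosomal protein (camera adjusted p = 3.94e-12) and proteasome genes (2.63e-09), the S phase (4.32e-08) and G2 and mitosis lists (4.32e-08), ADAR partners (4.35e-07), nuclear OXPHOS (6.57e-07), splicing (7.54e-07), paraspeckle (0.000172), mitochondrially encoded (0.000395), sterol (0.00121), RNA interference (0.0044) and glycolysis and hypoxia genes (0.00833). The other 13 lists had camera adjusted p = 0.0797 to 0.888, and for 2 of them, RNA sensors and recoding sites, the median, mean and test differed in sign. With an estimated correlation camera called 0 lists, with 2 below an unadjusted p of 0.05, and fry of limma called 0. Of the 21 named gene results for ADAR3 against ADAR1 that passed, 5 passed in all 6 fits with 1 library left out (ADAR, ADARB2, AMD1P3, BEST1 and ROCK1P1), SLC16A4-AS1 and HIGD1AP13 in 0, KCNJ9 in 1 and RGS11 in 2. The count of 58 genes was 15, 7 and 21 without ADAR1 replicate 1, 2 or 3 and 16 without ADAR3 replicate 3. The share of higher calls, 86.2%, was 54.9% with library quality weights (325 higher, 267 lower) and 64.8% with DESeq2 (188 higher, 102 lower).

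Between ADAR3 and ADAR2, 13 genes were higher with ADAR3, ADARB2 among them, and 1 lower, ADARB1, which leaves 12 besides the transgenes. UNC13A, a synaptic vesicle priming gene, was 2.80-fold higher, at 5.32 ± 0.22 against 1.88 ± 0.47 CPM (SD, n = 3) (adjusted p = 0.00637). BEST1 was 2.31-fold higher, NPHS1, the nephrin gene, 2.91-fold, VLDLR-AS1 2.72-fold and ROCK1P1 1.96-fold. SESN2 was 1.40-fold higher (adjusted p = 0.0462). Camera called 18 lists, 7 up and 11 down, with adjusted p = 0.298 to 0.611 with an estimated correlation. The G2 and mitosis list was lower with ADAR3 (median -0.17, camera adjusted p = 2.14e-14), with 0 genes past the test over all genes and 16 adjusted over the list alone, and so were glycolysis and hypoxia genes (median -0.24, camera adjusted p = 4.91e-07), with 0 and 12 lower. The p53 targets were higher (median 0.21, camera adjusted p = 7.55e-08), with 0 and 10. Also lower were ribosomal protein (camera adjusted p = 1.82e-12), heat shock (3.4e-08), proteasome (7.55e-08), nuclear OXPHOS (1.07e-06), ADAR partner (6.94e-06), S phase (1.45e-05), sterol (2.41e-05), splicing (3.13e-05) and paraspeckle genes (0.00618). Also higher were histone genes (0.000454), NF-kB targets (0.0015), zinc finger genes (0.00794), the integrated stress response (0.0119), immediate early genes (0.0221) and neuronal genes (0.0289). The other 14 lists had camera adjusted p = 0.0513 to 0.984, and for RNA sensors and recoding sites the median, mean and test differed in sign. With an estimated correlation camera called 0 lists, with 1 below an unadjusted p of 0.05, and fry of limma called 1. The medians of the splicing and paraspeckle lists, -0.10 and -0.11, turned to 0.00283 and 0.01 under quantile scaling, and that of G2 and mitosis was -0.11. The groups did not overlap in 16.0% of genes, where chance gives about 10%. Of the 8 named gene results that passed, ADARB1, ADARB2 and ROCK1P1 did so in all 6 fits with 1 library left out. The count of 14 was 1065, 3 and 290 without ADAR2 replicate 1, 2 or 3, 42 and 4 without ADAR3 replicate 1 or 3, and 4 with the 3 ADAR genes left out. More genes were lower than higher with DESeq2 (249 higher, 378 lower) and without ADAR2 replicate 1 (475 higher, 590 lower), and with no filter on low counts 410 were higher and 284 lower.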

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

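The tests of the stress genes, of carry-over, of the vector libraries as a batch, of transcript length in the higher genes and of leaving out the 2 libraries with the most plasmid reads were chosen only after the result was seen. Direct tests between enzymes called 7 genes for ADAR2 against ADAR1, 58 for ADAR3 against ADAR1 and 14 for ADAR3 against ADAR2, which drew attention because each is a difference seen directly between enzyme groups and not only against the vector. Reads outside annotated genes drew attention because no gene test uses them; they made up 8.31% ± 0.78 of entries in the ADAR1 group and 8.38% ± 0.30 in the ADAR3 group (SD, n = 3), against 6.93% ± 0.30 in the vector group and 7.52% ± 0.64 in the ADAR2 group. ADAR1 and ADAR3 were flagged because all 3 of their libraries lay above all 3 vector libraries. That alone fixes the exact permutation p against the vector at 0.1, the smallest that 3 against 3 allows (0.15 after Benjamini-Hochberg adjustment). The p therefore adds no support. ADAR2, which was not flagged, gave 0.2 (0.2 adjusted).

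For the 191 genes called in 1 direction in all 3 enzyme groups, simulated unchanged groups gave at most 0 such genes in 20 simulations. These drew each gene independently, with the same dispersion in all groups and new vector libraries. They therefore cannot decide whether the shared controls of these samples are the cause, which stays open. GC content or transcript length as the whole cause is argued against by 228 such genes with offsets for both, 140 among the 191. A part of it stays open. By the longest annotated transcript, the 118 higher genes had a median length of 6398 bases against 3665 in matched lists. Their GC content was 43.8% against 48.5% over all genes. Vector libraries from 1 culture or batch cannot be told apart from an effect of the inserts, because the batch would hold the vector group alone; the other groups had a spread at least 1.54 times that of the vector libraries. An effect of the inserts, or of the transfection load, stays open and untested. Without vector replicate 1, 2 or 3 only 2, 6 and 2 genes were called in all 3.

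Of the integrated stress response genes, CHAC1, TRIB3 and SESN2 were higher with ADAR3 than with ADAR1, with a median log2 difference of 0.55. Without ADAR3 replicate 3 the median was 0.44, and against ADAR1 replicates 1 and 2 alone it was 0.59. These are 3 of 30 listed genes, chosen because they passed in this comparison, so that neither that library nor the transgene load of ADAR1 replicate 3 can be told apart from an effect of the inserts. SESN2 stood at 133 CPM in vector libraries, 132 with ADAR3 and 89.7 with ADAR1, so that its difference is a lower level with ADAR1. A difference between the inserts stays open as a hypothesis.

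ADARB2 counts in the ADAR2 libraries exceeded the vector level by 4.43, 5.28 and 13.2 CPM. Reads of the ADARB1 insert placed on ADARB2 are argued against for reads of 36 bases or more, since 0 of 46305 windows of 50 bases in ADARB1 transcripts lay within 2 mismatches of an ADARB2 transcript, although 112 of 46680 windows of 25 bases did and the read length is not known. The highest excess was 2.99 times the lowest, and carry-over of ADARB2 reads from the ADAR3 libraries cannot be told apart from true expression, because carry-over can differ between libraries. The bound for this test was first set for a constant excess and was changed after the value was seen. Expression of the gene itself in response to ADAR2 stays open and was not tested. In the ADAR3 libraries ADARB1, at 41.1, 43.2 and 40.4 CPM, also lay above all 3 vector libraries, although it did not pass. Carry-over of ADARB1 reads from the ADAR2 libraries was not tested.

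The counts were set against all 10 divisions of each 6 libraries into 3 and 3, which are too few for a share under 0.05. The real counts and the highest of the other divisions were 966 and 0 for ADAR1, 735 and 0 for ADAR2 and 945 and 0 for ADAR3 against the vector. They were 58 and 0 for ADAR3 against ADAR1, and 14 and 0 for ADAR3 against ADAR2; in each of these 5 comparisons 1 division, the real one, gave as many. For ADAR2 against ADAR1 3 divisions gave at least the real 7. The highest, 924, set ADAR1 replicate 1 and ADAR2 replicates 1 and 2 against the other 3 libraries. It points to a structure of these samples other than which enzyme was transfected. Those 3 have the lowest transgene levels of the 6, at 11287, 15316 and 11909 CPM. The division with 188 genes, which set ADAR1 replicates 1 and 2 and ADAR2 replicate 1 apart, does not follow this order in full. Both divisions set the replicate 1 libraries against the replicate 3 libraries, which hold the most transgene reads, at 56575 and 61364 CPM. Replicate number and transgene level cannot be told apart here, and the cause is open.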

How the results depend on the processing

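Of these alternatives, DESeq2, a mean of at least 5 CPM, quantile normalization, no abundance trend, robust hyperparameters, library quality weights, GC and length offsets, thinning and leaving out the 2 libraries with the most plasmid reads were chosen after the data were seen. The 3 transgene results passed under each setting run, and no single gene that was called changed sign. For ADAR3 against ADAR2 more genes were higher than lower (13 to 1, the transgenes included), and more were lower with DESeq2 (249 to 378) and without ADAR2 replicate 1 (475 to 590), and the medians of the paraspeckle and splicing lists changed sign under quantile normalization. That setting moved the medians of 9 of 16, 13 of 19 and 11 of 18 lists called for ADAR3 against the vector, ADAR1 and ADAR2 by over 1.5 times, 8, 12 and 10 of them nearer 0. Against the vector the majority, which was near even, turned under several settings, such as DESeq2 for ADAR3 (829 higher, 1052 lower) and no filter for ADAR2 (768 higher, 595 lower). Values follow the order ADAR1, ADAR2 and ADAR3 against the vector, unless a comparison is named. The cause of each change was not tested. No filter on low counts gave 1510, 1363 and 1874 genes, 10 lists for ADAR2, 29 genes for ADAR2 against ADAR1, 478 for ADAR3 against ADAR1, 694 for ADAR3 against ADAR2 and 453 shared by all 3. No abundance trend gave 495, 356 and 192, and 59 shared. Library quality weights gave 4721, 2650 and 3812, 592 for ADAR3 against ADAR1, 51 for ADAR3 against ADAR2 and 1162 shared. DESeq2 gave 1299 for ADAR2, 1881 for ADAR3, 290 and 627 for ADAR3 against ADAR1 and ADAR2, and 397 shared. A 2-fold minimum gave 127, 65 and 70, and 23 and 9 for ADAR3 against ADAR1 and ADAR2. Fits of only the 2 groups compared gave 3090, 222 and 3701, and 103 and 2. Without the 2 libraries with the most plasmid reads there were 2540, 3259 and 3332 genes, 197 and 554 for ADAR3 against ADAR1 and ADAR2, 1071 shared, 15 lists for ADAR2 and 11 for ADAR2 against ADAR1. ADAR3 against ADAR2 gave 39 genes with a mean of at least 5 CPM, 28 with robust hyperparameters, 8 after thinning and 4 without the 3 ADAR genes. ADAR2 against ADAR1 gave 4 genes with robust hyperparameters, 4 without the 3 ADAR genes, which took the share of higher calls from 28.6% to 0%, and 4 lists with quantile normalization. An estimated inter-gene correlation gave 0 lists in each of the 6 comparisons.

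A replicate block gave 1146 genes for ADAR2, 1721 for ADAR3, 122 and 134 for ADAR3 against ADAR1 and ADAR2, and 341 shared, and took no other count past 1.5 times. Whether the numbers pair the libraries is not settled. Of 18 same-numbered pairs 5 correlated above 0.1 (r from -0.08 to 0.35), each of them between enzyme groups. The replicate 3 libraries of the enzyme groups correlated at 0.354, 0.228 and 0.153, but they also hold the most transgene reads. Libraries of unlike number reached 0.198, for ADAR1 replicate 1 and ADAR2 replicate 2. In all, 6 of 12 libraries correlated best with their own number, a hint from the data only.

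Leaving out 1 library at a time gave 111 to 767, 32 to 2722 and 5 to 802 genes, 3 to 8 for ADAR2 against ADAR1, 7 to 54 for ADAR3 against ADAR1, 3 to 1065 for ADAR3 against ADAR2 and 2 to 753 shared. Lists ranged from 8 to 12, 6 to 16 and 15 to 16 against the vector, and from 2 to 18, 17 to 20 and 14 to 21 between enzymes. The log2 change of ADAR ranged from 4.12 to 5.47, that of ADARB1 from 8.90 to 10.39 and that of ADARB2 from 12.84 to 13.47. Each of the 3 vector libraries moved all 3 counts by over 1.5 times, and the libraries of the enzyme groups that did so are named with the counts above. Of 5250 results for single genes, 4090 kept their side of the threshold, 1151 lost it and 9 gained it. The planned pseudocount of 0.1 and array weights for the lists were not run, since the files hold counts. Small changes are found in part, since 28 of 65 simulated changes of 0.5 on the log2 scale were found for ADAR1.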

Other observations

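The length test of the genes higher in all 3 enzyme groups was chosen only after that list was seen. Length was that of the longest annotated transcript of each gene, which need not be the one these cells express. By this measure those 118 genes had long transcripts. The median over the 113 with a known length was 6398 bases, against 3665 for 10000 random lists matched on expression, at percentile 100 of those lists. The 73 genes lower in all 3 had a median of 3542.5 bases against 3946.5 in matched lists, percentile 10.4, which gives no sign of shorter transcripts. GC content was 43.8% in the higher genes and 48.5% over all tested genes.

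AMD1P3 stood at 13.2 CPM in vector libraries, 9.87 with ADAR1, 3.37 with ADAR2 and 3.60 with ADAR3. KCNJ9 and RGS11 followed the same order of groups, at 32.4, 24.4, 8.73 and 10.8 CPM for KCNJ9. Within the ADAR2 and ADAR3 groups AMD1P3, KCNJ9 and RGS11 were highest in replicate 3, the library with the most transgene reads. KCNJ9 stood at 11.9 and 14.7 CPM there. Within the ADAR1 group these genes were lowest in replicate 3, with KCNJ9 at 22.2 CPM. The ADAR2 and ADAR3 libraries were also the deeper ones, with 26.5 M to 38.8 M gene counts against 20.7 M to 23.3 M in the other groups. After thinning to the smallest library all 7 genes called between ADAR2 and ADAR1 were kept. A batch shared by the ADAR2 and ADAR3 groups, which the labels do not give, cannot be told apart from an effect of the inserts. ROCK1P1 stood at 34.1, 14.6, 17.0 and 33.6 CPM. Values for single libraries of IFNL1, IFNL2, IFNL3, IFNB1, CXCL10 and CXCL11 were lowest in the library with the most transgene reads in 3 of 3 enzyme groups. In ADAR2 replicate 3 IFNL1 and CXCL10, at 10.2 and 4.25 CPM, lay below all 3 vector libraries. IFNB1, at 5.48 CPM, lay within the range of the vector libraries.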
